A study of Homo sapiens with 6 samples.

How the data were processed

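Total RNA from CaSki cells was sequenced in 6 libraries, 3 of cells transfected with a control siRNA and 3 of cells transfected with an siRNA against ER-α36, and the group of each library was taken from its label. The deposited tables hold 1 FPKM value per gene and library, and the submitters' processing notes name TopHat, Cufflinks and the genome build hg19, with no version or setting. Whether the authors counted read pairs or single reads, and which annotation they used, is not given in the sources used here; FPKM here means the deposited length- and depth-normalised value. All 6 columns were used.

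Each table lists 28217 Ensembl genes. Symbols came from a table of gene names for 27813 genes and from GENCODE 29 for 195, and 209 kept their identifier; entries with the same symbol were summed. The depth was read from the values themselves. A deposited value times the merged exon length of the gene in GENCODE 29 is a whole multiple of 1 constant per library, which gives the number of reads that the library was normalised to, from 16863174 to 17444727. Of the low values used for this, 94.8% to 95.1% came out whole within 0.01 read, and reads were recovered for 26230 genes (93.0%), which hold 88.8% to 88.9% of the normalised reads. The lengths match GENCODE 29, an annotation of GRCh38, although the notes name hg19. The tables hold no coordinates, so coordinates are those of GENCODE 29 on GRCh38, and the build of the alignment was left open. With no stated strand setting, overlapping and antisense genes and genes with near-identical copies may share reads.

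Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12087 genes). Values were taken as log2(FPKM + 1), with a pseudocount of 1 and the authors' scaling, and fitted with limma 3.58.1 in R 4.3.3 (eBayes with a variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). No replicate block was used. ESR1 and HMGA2 lie below the filter and were taken from the same fit without it. For single genes an exact permutation test of 3 against 3 cannot go below p = 0.1. The test was checked on simulated data in 10 runs of 12042 genes with known changes. It recovered 96.1% of 2-fold and 27.3% of 1.3-fold changes, and 9.10% of its calls were false. False calls made up 70.9% of calls on genes under 50 reads and 1.28% of calls on genes with 50 reads or more. Genes were drawn independently at an assumed dispersion of 0.005, with 969 changes of 2-fold and 983 of 1.3-fold over the 10 runs. The shares of false calls depend on these settings, which were not matched to the data.

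Gene lists were fixed before the data were examined: hormone receptors, estrogen response, EGFR family, interferon response, NF-kB and inflammation, cell cycle, replication histones, ERK output, YAP, Wnt, NRF2, p53, ATF4 and FOXO targets, the unfolded protein response, apoptosis, hypoxia and glycolysis, cholesterol synthesis, HMGA and let-7 linked genes, mesenchymal, epithelial junction, squamous differentiation and basal squamous genes, invasion proteases, and markers of fibroblasts, endothelium, leukocytes and glandular cells. The 23 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Over the other 9 splits of the 6 libraries the test with the preset correlation called 1 to 5 lists, and these splits keep part of any difference between the groups. Called members were also counted with the p-values adjusted over the list alone. No list was chosen by the study on these libraries.

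The genes to be named were ESR1, HMGA2, the 12 largest increases and the 12 largest decreases among called genes whose groups did not overlap, and up to 4 called members of each list with the largest absolute change; sex-linked marker genes were left out. Some genes that the rule names are not reported here. A further 15 rising and 25 falling protein-coding genes, with at least 5 FPKM and 50 reads, were added after the values had been seen, as were other list members given as examples and the interferon-induced genes outside the list.

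Alternatives fixed at the same time as the lists were the replicate number as a block, leaving out each library, rescaling by median ratios, quantile normalization, a pseudocount of 0.1, no variance trend, no filter, a filter of 5 FPKM, a 2-fold minimum, and, for the lists, an estimated correlation and fry. Those added after the data had been seen were genes of at least 50 recovered reads, limma's voom on the recovered reads, and genes without either of the 7-base words. Alternatives planned for count tables do not apply to FPKM.

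For the search of 3′ UTRs, the 3′ UTR of 1 principal protein-coding transcript per gene was taken from GENCODE 29, with a minimum of 50 bases. Over 7090 genes with at least 5 FPKM, the log2 fold change was regressed on the presence of each of 15821 words of 7 bases found in at least 50 genes, with 3′ UTR length, GC content and expression as covariates. The highest absolute t in 100 shuffles of the fold changes over genes served as the chance level. The search recovered a word planted in shuffled data as its top word. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for this and for the figures. The siRNA sequences are not given in the sources used here.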

Results

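RNA sequencing compared the transcriptomes of CaSki cells with and without knockdown of ER-α36. CaSki is an established squamous cervical cancer line that carries human papillomavirus, and ER-α36 is a short variant of the estrogen receptor α, encoded by ESR1. The control group held 3 libraries of cells given a non-targeting siRNA, and the knockdown group held 3 libraries of cells given an siRNA against ER-α36. Transfection lasted 48 h, and all cells received 1 nM estradiol for 24 h in medium without phenol red that held 10% serum. The question was which genes depend on ER-α36 in estradiol-treated cervical cancer cells. The deposited values are FPKM (fragments per kilobase of exon, scaled to the depth of the library) for 28217 genes. The control libraries were normalised to 16863174, 17334336 and 17114392 reads, and the knockdown libraries to 17430639, 17444727 and 17019457. At these depths 1 read on a gene with 1 kb of exon is worth 0.0573 to 0.0593 FPKM. The submitters describe biological as well as experimental triplicates without saying which libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise: the chi-square per gene was 3.71 to 13.2 within groups and 14.7 to 35.2 between them. Levels are given below as mean ± SD over n = 3 libraries, and fold changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of low genes.

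ESR1, the gene of the targeted variant, was close to undetected in all 6 libraries. Its level was 0.0131, 0.0127 and 0.0257 FPKM in control replicates 1, 2 and 3, and 0.0168, 0.00421 and 0.0129 FPKM in knockdown replicates 1, 2 and 3. After correction for depth these values stand in the ratio of the whole numbers 3, 3, 6, 4, 1 and 3, the pattern that a few reads per library give. Group means of 0.0172 ± 0.0074 and 0.0113 ± 0.0065 FPKM did not differ beyond the spread between replicates (log2 fold change -0.01, SE 0.019, limma adjusted p = 0.842; exact two-sided permutation test p = 0.5, where 0.1 is the smallest p that 3 against 3 can give). The gene spans chromosome 6, 151656691 to 152129619, in the GENCODE 29 annotation of GRCh38, and a gene-level value counts all of its transcripts. A difference in ER-α36 was therefore not detectable at this depth, and the values do not check the labels of the knockdown. The progesterone receptor gene PGR and TFF1, both classical estrogen-induced genes, are not among the 28217 genes with values, so they could not be tested. Every listed gene is above 0 in at least 1 library, so the absent genes may have had no reads.

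Knockdown cells had lower levels of 18 of 27 interferon-stimulated genes, of 8 of 16 NRF2 targets, and of single genes such as MCFD2, ELK3, FGF2 and IL6. Higher levels were found for 10 of 28 cell cycle and DNA replication genes, for 3 of 8 replication histone genes, and for single genes such as OGFR, GANAB, TPM4 and ADAM15. These 4 lists were called by camera with a preset correlation and lost their call with an estimated one (adjusted p = 0.422 with an estimated correlation for each). Of 12087 genes with a mean of at least 1 FPKM, 2371 changed (limma, Benjamini-Hochberg adjusted p under 0.05): 1089 rose and 1282 fell. On the log2(FPKM + 1) scale, which shrinks the changes of low genes, 2329 of the called genes (98.2%) moved by less than 2-fold, and of the other 42, 6 rose and 36 fell. With a pseudocount of 0.1, 80 called genes moved by at least 2-fold (19 higher, 61 lower). In 4691 genes (38.8%) the groups did not overlap, where chance gives 10%. The count depended on single libraries: 1025 genes were called without control replicate 1, 1165 without control replicate 3, 937 without knockdown replicate 1, 1070 without knockdown replicate 2 and 3742 without knockdown replicate 3, which lay nearest to the controls on the leading principal component. Reads could be recovered for 2174 of the called genes, and 93 of these averaged under 50 reads, a class in which most calls on simulated data were false. The simulation changed a far smaller share of genes than was called here, so its share of false calls need not hold for these 93.

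Among protein-coding genes OGFR rose the most on the log2(FPKM + 1) scale, from 14.7 ± 1.51 to 41.8 ± 2.81 FPKM (log2 fold change 1.45, SE 0.082, limma adjusted p = 0.000112). OGFR, the opioid growth factor receptor, lies on chromosome 20, 62804835 to 62814000 (GENCODE 29, GRCh38). GANAB, the catalytic subunit of glucosidase II in the endoplasmic reticulum, rose from 77.3 ± 4.30 to 197 ± 10.7 FPKM (1.34, SE 0.063, adjusted p = 5.97e-05). TPM4, an actin-binding tropomyosin, rose from 42.4 ± 0.88 to 89.3 ± 4.43 FPKM, and CDK14, a cyclin-dependent kinase, from 3.62 ± 0.17 to 9.26 ± 1.11 FPKM. The metalloprotease gene ADAM15 rose from 24.0 ± 1.07 to 48.9 ± 4.14 FPKM. RGS19, a regulator of G protein signalling, rose from 5.74 ± 0.19 to 12.3 ± 0.56 FPKM, and MESD, a chaperone of LDL receptor family proteins, from 5.22 ± 0.50 to 10.7 ± 0.15 FPKM. HSPA2, a heat shock protein 70 gene, and IGFBPL1 rose from near 1 FPKM, with log2 fold changes of 0.89 and 0.93. The 12 largest increases also held the long noncoding RNA LINC01667 and the pseudogene AC018692.3, which overlap on chromosome 21 and may share reads, and a pseudogene with no symbol that averaged 3.83 reads.

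MCFD2, a cargo receptor subunit for coagulation factors, fell from 27.4 ± 1.43 to 9.95 ± 0.37 FPKM (log2 fold change -1.38, SE 0.058, limma adjusted p = 5.25e-05). It lies on chromosome 2, 46901870 to 46941855 (GENCODE 29, GRCh38). ELK3, an ETS transcription factor, fell from 10.7 ± 1.26 to 3.55 ± 0.45 FPKM (-1.36, SE 0.10, adjusted p = 0.000328). OAS2, an interferon-induced oligoadenylate synthetase, fell from 38.7 ± 8.37 to 15.5 ± 3.88 FPKM. Most of the other 9 of the 12 largest decreases were short genes such as MIR421, with 9, 5 and 9 reads in the controls and 0, 1 and 0 in the knockdown libraries, and MIR27B, with 6, 7 and 4 against 2, 1 and 0. These counts are a handful of reads, and 2 of the 9 have neither an annotated length nor recovered reads, so a wider set of 15 rising and 25 falling protein-coding genes with at least 5 FPKM and 50 reads was chosen after the values had been seen. In that set the growth factor FGF2 fell from 8.38 ± 0.58 to 3.33 ± 0.42 FPKM and STX6, a syntaxin of the trans-Golgi network, from 10.6 ± 0.60 to 4.19 ± 0.05 FPKM. CNOT11, a CCR4-NOT deadenylase subunit, fell from 19.4 ± 0.24 to 8.56 ± 0.05 FPKM, and CBFB, the partner of RUNX transcription factors, from 72.6 ± 4.48 to 37.1 ± 1.83 FPKM. SRPRA, a subunit of the signal recognition particle receptor, the phospholipid-metabolising enzyme gene PLAAT2 and LEO1, a subunit of the PAF1 complex, had log2 fold changes of -0.99, -1.19 and -1.01. Rising genes of the set included NOLC1, a nucleolar phosphoprotein, from 34.6 ± 1.29 to 62.7 ± 4.20 FPKM, and G3BP2, a stress granule protein, from 25.4 ± 1.18 to 44.7 ± 3.15 FPKM.

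**Figure D1:**
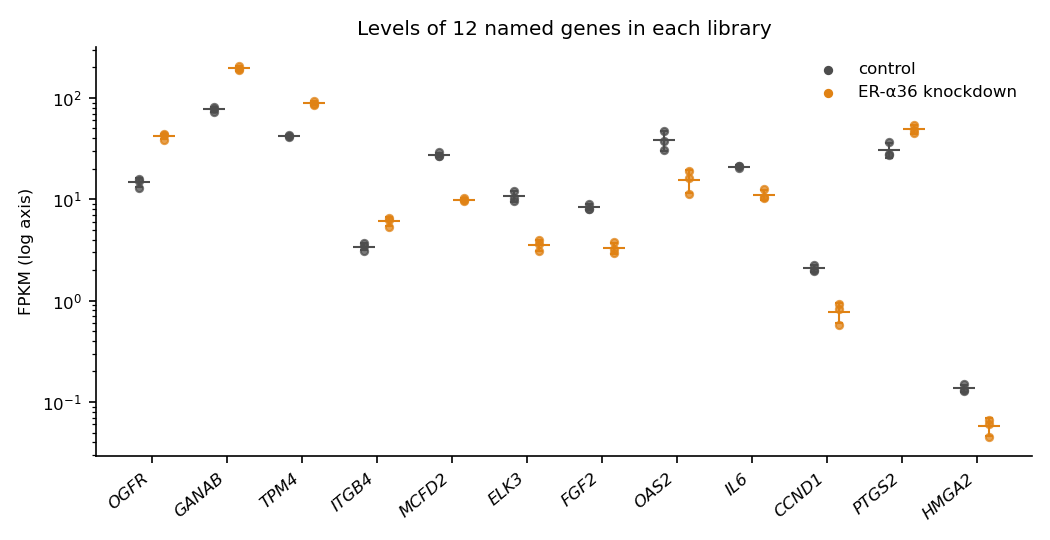
FPKM on a log axis for 12 named genes, with 1 point per library, a horizontal bar at the mean and a whisker of 1 SD (n = 3 libraries per group). Knockdown libraries lie above all control libraries for OGFR, GANAB, TPM4, ITGB4 and PTGS2 and below them for the other genes; HMGA2 lies below the filter of 1 FPKM.

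The 3′ untranslated regions of the called genes differed from those of other genes in a pair of 7-base words. CTGATGA occurred in 334 of the 1173 falling genes whose 3′ UTR could be searched (28.5%), in 50 of 986 rising genes (5.07%) and in 773 of 8207 genes not called (9.42%; two-sided Fisher's exact test of falling genes against genes not called, p = 7.4e-64). TCGGAGA occurred in 66 of the 986 rising genes (6.69%), in 15 of the 1173 falling genes (1.28%) and in 127 of the 8207 not called (1.55%; two-sided Fisher's exact test of rising genes against genes not called, p = 9.2e-19). Genes are not independent replicates, and the words were picked from a search of all 7-base words in the same data. Of the 25 falling protein-coding genes of the wider set, 12 carry CTGATGA, among them MCFD2, ELK3, STX6, FGF2, CNOT11, IFI44L, TMEM263, SRPRA, POLR1F, CBFB and TMEM181. Of the 15 rising genes, 5 carry TCGGAGA: CDK14, NOLC1, BICD2, G3BP2 and PCNX3; TPM4 also carries it. CDK14 carries CTGATGA as well. Without the genes that carry either word, 870 genes rose and 831 fell, an alternative added after the data had been seen.

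Interferon-stimulated genes fell together. Of 27 measured members 18 fell, 0 rose and 9 did not pass the test; adjusted over the list alone, 21 fell. IFIT3, whose product limits viral translation, dropped from 72.2 ± 15.98 to 29.9 ± 7.74 FPKM, RSAD2, the antiviral enzyme viperin, from 4.15 ± 1.01 to 1.34 ± 0.27 FPKM, and IFI44 from 22.9 ± 3.44 to 10.2 ± 2.58 FPKM. ISG15, a ubiquitin-like modifier, and IFI6 were the most abundant, at 371 and 551 FPKM in the controls and 233 and 302 FPKM in the knockdown libraries. The median log2 fold change was -0.64 (camera with a preset correlation, adjusted p = 8.5e-09), with adjusted p = 0.422 with an estimated correlation, which was 0.783, and fry gave an adjusted p of 0.0502. With the preset correlation the list was also called in 5 of the 9 other splits of the 6 libraries, with adjusted p down to 2.0e-14, so its p does not measure the difference between the groups alone. IFITM1 and TRIM22, interferon-induced genes outside the list, fell from 44.1 ± 6.93 to 20.6 ± 3.28 FPKM and from 7.92 ± 1.45 to 3.01 ± 0.66 FPKM. The libraries of a group differed as well: the mean log2 level of the list was 4.95, 4.70 and 5.11 in the controls and 4.35, 4.08 and 4.44 in the knockdown libraries. Among the named members, IFIT1, IFIT2, IFIT3 and IFI44L were not called when the filter on low values was dropped.

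**Figure D2:**
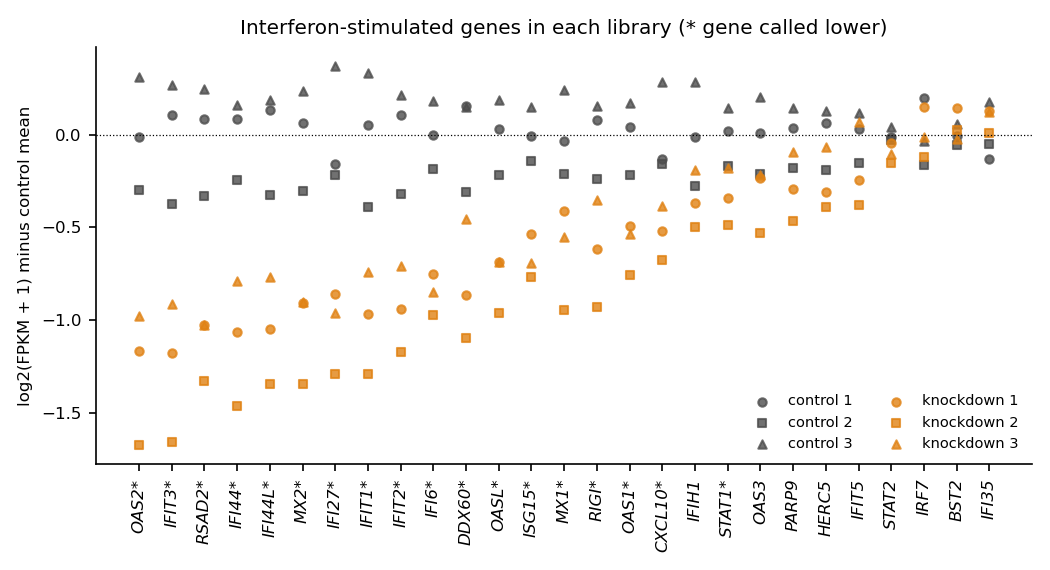
log2(FPKM + 1) minus the mean of the 3 controls for the 27 measured interferon-stimulated genes, ordered by their mean in the knockdown libraries; each point is 1 gene in 1 library, and shapes mark replicates 1 to 3. Asterisks mark the 18 genes called lower, and the knockdown libraries averaged -0.57, -0.84 and -0.48 over all 27.

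Cell cycle and DNA replication genes were modestly higher. Of 28 measured members 10 rose, 1 fell and 17 did not pass; adjusted over the list alone, 12 rose and 1 fell. CDT1, which licenses replication origins, rose from 26.8 ± 1.98 to 40.8 ± 3.81 FPKM, and the helicase subunit genes MCM5 and MCM7 from 27.3 ± 2.22 to 38.5 ± 2.34 and from 104 ± 5.80 to 143 ± 6.23 FPKM. BIRC5, encoding survivin, rose from 35.6 ± 2.41 to 48.2 ± 2.81 FPKM. CCNE1, encoding cyclin E1, fell from 9.54 to 6.85 FPKM. The list median was 0.13 (adjusted p = 0.00058), and adjusted p = 0.422 with an estimated correlation. Replication histone genes, whose transcripts mostly lack a poly(A) tail, went the same way: 3 of 8 rose and 0 fell, and adjusted over the list alone 4 rose (list median 0.23, adjusted p = 0.0194; adjusted p = 0.422 with an estimated correlation). H2BC5 rose from 9.23 ± 0.98 to 16.3 ± 0.17 FPKM. Gene-level values do not tell histone transcripts with a poly(A) tail from those without. A link of these histone rises to DNA replication was therefore not tested. The call of the histone list was lost without knockdown replicate 1 (adjusted p = 0.0671) and without knockdown replicate 3 (adjusted p = 0.0531).

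Targets of NRF2, the transcription factor of the oxidative stress response, were lower. Of 16 measured members 8 fell, 1 rose and 7 did not pass; adjusted over the list alone, 9 fell and 1 rose. The aldo-keto reductase genes AKR1B10 and AKR1C2 fell from 3.59 ± 0.74 to 0.89 ± 0.19 FPKM and from 64.1 ± 5.97 to 40.5 ± 2.09 FPKM, and TXNRD1, encoding thioredoxin reductase, from 143 ± 6.20 to 99.2 ± 5.09 FPKM. The exception, ME1, encoding a cytosolic malic enzyme, rose from 12.6 to 14.96 FPKM. The list median was -0.26 (adjusted p = 0.00125), with adjusted p = 0.422 with an estimated correlation; over its 12 members without either 7-base word the median was -0.17.

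Transcriptional targets of ERK signalling and of YAP also lay lower on average. Among 17 ERK output genes 7 fell and 0 rose, and adjusted over the list alone 9 fell (median -0.25, adjusted p = 0.0161; adjusted p = 0.422 with an estimated correlation). CCND1, encoding cyclin D1, fell from 2.08 ± 0.16 to 0.78 ± 0.18 FPKM and FOSL1, an AP-1 subunit, from 15.7 ± 0.60 to 11.3 ± 0.17 FPKM; DUSP4 and SPRED1, which restrain ERK signalling, fell by 0.43 and 0.41 on the log2 scale and both carry CTGATGA. The call of this list was lost without genes carrying either word (adjusted p = 0.104), where the median over its 13 members was -0.12, and at a filter of 5 FPKM (adjusted p = 0.471). Of 14 YAP targets 6 fell and 1 rose, as they did when adjusted over the list alone (median -0.22, adjusted p = 0.0342; adjusted p = 0.422 with an estimated correlation). F3, encoding tissue factor, fell from 47.7 ± 2.60 to 31.3 ± 3.01 FPKM, and AMOTL1, an angiomotin family gene that carries CTGATGA, rose from 1.79 ± 0.07 to 2.48 ± 0.12 FPKM. The calls of AMOTL1, DUSP4 and SPRED1 were lost with no filter on low values and when single libraries were left out. The YAP call was lost with quantile normalization (adjusted p = 0.0568), without control replicate 2 (0.0541), without knockdown replicate 1 (0.0545) and without knockdown replicate 3 (0.0680).

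Estrogen response genes moved in both directions. Of 16 measured genes that estrogen receptor signalling raises in breast cancer cells, 4 rose, 4 fell and 8 did not pass, and the counts were the same adjusted over the list alone (camera adjusted p = 0.563). CA12, a carbonic anhydrase, and SIAH2, a ubiquitin ligase, rose from 6.73 ± 0.45 to 10.2 ± 0.07 FPKM and from 7.87 ± 1.19 to 11.4 ± 0.75 FPKM, whereas NRIP1, a nuclear receptor corepressor, fell from 5.40 ± 0.53 to 3.58 ± 0.67 FPKM alongside CCND1. Of 9 hormone receptor genes, the vitamin D receptor gene VDR rose by 0.29 and the glucocorticoid receptor gene NR3C1, which carries CTGATGA, fell by 0.34 on the log2 scale; adjusted over the list alone, 3 rose and 2 fell (adjusted p = 0.563). In the EGFR family the ligand gene EPGN fell from 42.8 ± 3.79 to 28.4 ± 2.71 FPKM and the receptor gene ERBB3 rose from 3.94 ± 0.11 to 4.81 ± 0.31 FPKM, among 8 members (adjusted over the list alone, 2 rose and 1 fell; adjusted p = 0.607). Of these genes SIAH2, NRIP1, VDR, NR3C1 and ERBB3 lost their call with no filter on low values or when single libraries were left out.

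Inflammatory genes split as well. Of 17 cytokine and NF-kB target genes 5 rose and 4 fell, and adjusted over the list alone 6 rose and 5 fell (adjusted p = 0.563). The cytokine gene IL6 fell from 21.0 ± 0.66 to 11.2 ± 1.20 FPKM (log2 fold change -0.86, SE 0.075, limma adjusted p = 0.000574). PTGS2, encoding cyclooxygenase-2, rose from 30.6 ± 5.11 to 49.1 ± 4.53 FPKM, and the chemokine genes CXCL1 and CXCL3 rose from 15.7 ± 0.61 to 24.7 ± 2.14 and from 1.48 ± 0.14 to 2.82 ± 0.18 FPKM. Apoptosis regulators were divided 3 to 3 among 17 (4 and 4 adjusted over the list alone; adjusted p = 0.583): the anti-apoptotic gene BCL2L1 rose from 11.8 ± 1.12 to 15.8 ± 1.67 FPKM, and MCL1, also anti-apoptotic, which carries CTGATGA, fell from 114 ± 4.76 to 74.0 ± 3.63 FPKM. The calls of PTGS2 and BCL2L1 were lost with no filter on low values, and that of BCL2L1 also when single libraries were left out.

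HMGA2, an architectural chromatin protein repressed by let-7 microRNAs, lay below the filter, at 0.137 ± 0.012 FPKM in the controls and 0.058 ± 0.012 FPKM in the knockdown libraries. It had 39, 35 and 34 reads in the controls and 12, 18 and 16 in the knockdown libraries. Its log2(FPKM + 1) difference of -0.10 (SE 0.026) had a limma adjusted p of 0.10 over all genes without a filter, while voom on the recovered reads, added after the data had been seen, gave a log2 fold change of -1.24 with adjusted p = 0.0123. The gene lies on chromosome 12, 65824131 to 65966295 (GENCODE 29, GRCh38). Of 8 measured HMGA and let-7 linked genes 4 fell (among them IGF2BP2, NRAS and MYC, with log2 fold changes of -0.34, -0.24 and -0.22) and 0 rose, as when adjusted over the list alone; the list was not called by camera with the preset correlation (adjusted p = 0.129), but was called lower with no filter on low values (adjusted p = 0.00745) and by fry (adjusted p = 0.0289). IGF2BP2, NRAS and MYC lost their calls when single libraries were left out, and MYC also with median-ratio scaling.

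Few genes of epithelial and mesenchymal state passed the test. Among 14 junction and simple epithelial genes JUP, encoding plakoglobin, rose from 18.4 ± 1.35 to 24.7 ± 1.98 FPKM and EPCAM from 5.76 ± 0.33 to 7.73 ± 0.54 FPKM, with 0 falling (also 2 and 0 adjusted over the list alone; camera adjusted p = 0.262, and fry adjusted p = 0.0427). Of 11 mesenchymal genes the repressors of E-cadherin SNAI1 and ZEB1 fell, by 0.32 and 0.37 on the log2 scale, and 0 rose (also adjusted over the list alone; adjusted p = 0.589, with a median of 0.00475 and a mean of -0.04). ITGB4, the integrin β4 chain of hemidesmosomes, rose from 3.42 ± 0.29 to 6.07 ± 0.63 FPKM and DST, a plakin, fell from 2.08 ± 0.15 to 1.40 ± 0.25 FPKM among 10 basal squamous genes (the same 1 and 1 adjusted over the list alone; adjusted p = 0.589, with a median of -0.00059 and a mean of 0.04). CNFN was the 1 of 5 squamous differentiation genes to rise, also adjusted over the list alone (adjusted p = 0.237). Among 11 invasion proteases and inhibitors MMP2 fell from 4.42 ± 0.34 to 2.90 ± 0.02 FPKM while MMP14, which activates it, rose from 27.7 ± 1.31 to 34.5 ± 1.55 FPKM along with SERPINE2 (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.272). The calls of JUP, SNAI1, ZEB1, DST, CNFN and SERPINE2 were lost with no filter on low values and, except for JUP, when single libraries were left out. CNFN was not called by voom either (adjusted p = 0.110).

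The lists of cholesterol synthesis, hypoxia and glycolysis, p53, the unfolded protein response, ATF4 and FOXO were not called by camera with the preset correlation over all 6 libraries and the filter of 1 FPKM. MSMO1, an enzyme of cholesterol synthesis, fell from 29.2 ± 3.69 to 22.6 ± 0.68 FPKM, and 5 of 20 cholesterol genes fell with 0 rising, also adjusted over the list alone (adjusted p = 0.135; called with no filter, adjusted p = 0.0440, and by fry, adjusted p = 0.0190). NDRG1, CA9 and ADM rose among 22 hypoxia and glycolysis genes, by 0.58, 0.42 and 0.32 on the log2 scale (0 and 0 adjusted over the list alone; adjusted p = 0.129; called with no filter, adjusted p = 0.0440, and without knockdown replicate 3, adjusted p = 0.0158). Of 18 p53 targets 6 fell and 2 rose, among them CDKN1A, encoding the cell cycle inhibitor p21, from 74.1 ± 4.91 to 56.1 ± 7.30 FPKM, and the repair gene XPC, from 6.91 ± 0.13 to 9.46 ± 0.26 FPKM (8 fell and 2 rose adjusted over the list alone; adjusted p = 0.280, and fry adjusted p = 0.0427). The chaperone genes CALR, HSPA5 and CRELD2 rose and SEL1L, which carries CTGATGA, fell among 19 unfolded protein response genes (the same 3 and 1 adjusted over the list alone; adjusted p = 0.296). CHAC1, SLC7A11, SESN2 and MTHFD2 fell and PHGDH rose among 19 ATF4 targets (4 fell and 3 rose adjusted over the list alone; adjusted p = 0.296). IRS2 and ERBB3 rose among 10 FOXO targets (also 2 and 0 adjusted over the list alone; adjusted p = 0.503). Only 4 Wnt targets were measured, too few for the test, and NOTUM rose by 0.28. The calls of MSMO1, NDRG1, CA9, ADM, CDKN1A, CALR, HSPA5, CRELD2, CHAC1, SLC7A11, SESN2, PHGDH, IRS2, ERBB3 and NOTUM were lost when single libraries were left out. That of ADM was lost also with median-ratio scaling (adjusted p = 0.0505) and those of HSPA5 and SESN2 with quantile normalization.

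**Figure D3:**
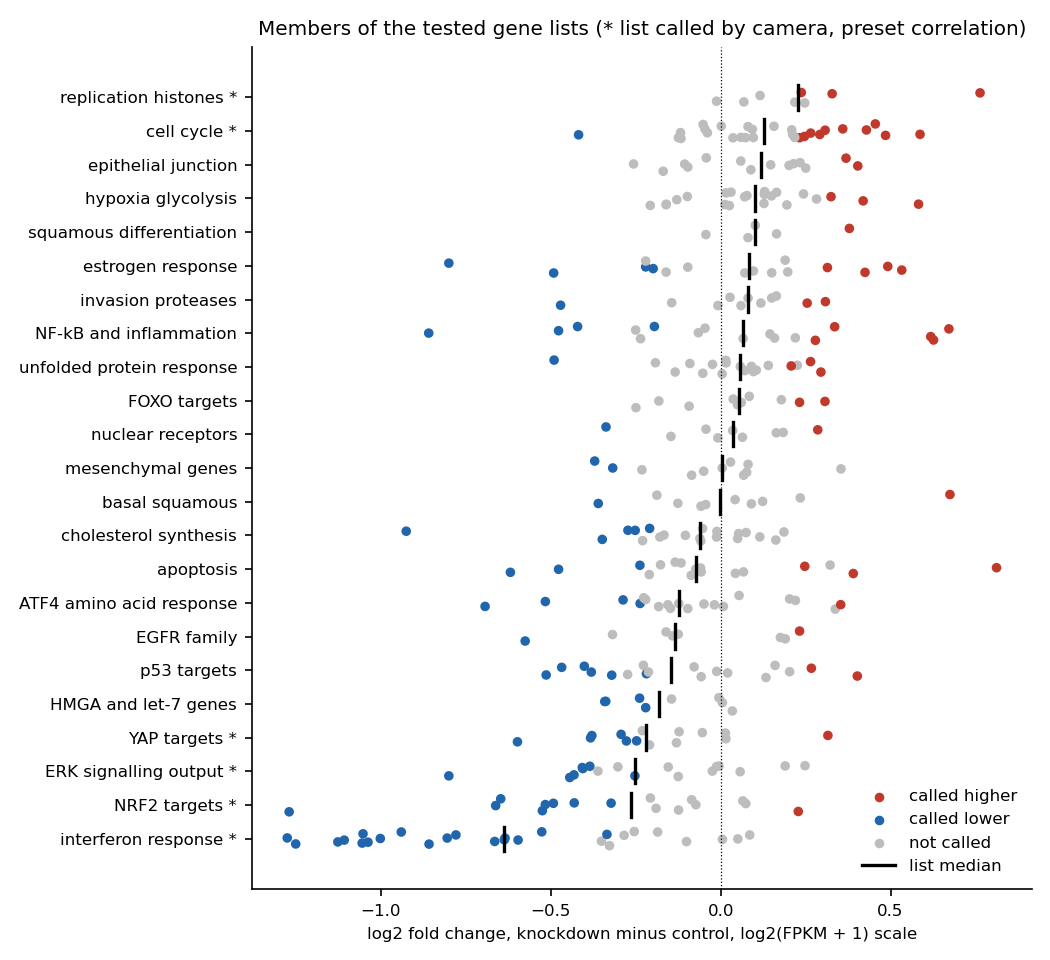
log2 fold change (knockdown minus control, log2(FPKM + 1) scale) of each measured member of the 23 tested lists, with 1 point per gene, coloured by its limma call, and a bar at the list median. The interferon list has the lowest median (-0.64) and replication histones the highest (0.23); asterisks mark the 6 lists called by camera with the preset correlation, 0 of which were called with an estimated correlation.

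Markers of other cell types were scarce. Of 12 fibroblast, 10 endothelial, 12 leukocyte and 12 glandular markers, 1 in each set reached 1 FPKM: COL1A1 at 1.55, the transcription factor gene ERG at 1.46, CD14 at 23.8 and PAX8 at 1.502 FPKM. ERG, which carries TCGGAGA, rose from 1.13 ± 0.17 to 1.78 ± 0.15 FPKM (limma adjusted p = 0.0303), a call lost with no filter on low values (adjusted p = 0.106) and without control replicates 2 or 3 or any 1 of the knockdown libraries, and the next endothelial marker, PECAM1, averaged 0.652 FPKM. The summed FPKM of each set in controls and knockdown libraries was 2.25 and 2.09 for fibroblasts, 2.15 and 2.77 for endothelium, 23.9 and 24.8 for leukocytes, and 1.70 and 1.55 for glandular cells.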

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

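The genes of at least 50 reads, voom and word-free alternatives were chosen after seeing the data. The count of 2371 changed genes (1089 higher, 1282 lower) stayed within 1.5 times under median-ratio scaling, quantile normalization, a pseudocount of 0.1, no variance trend, a filter of 5 FPKM, genes of at least 50 reads (2599) and voom (2730). Other scalings moved the share of higher calls from 45.9% to at most 51.0%. With no filter 27962 genes were tested and 935 called (438 higher, 497 lower), and 878 of the 2371 kept their call and direction. A 2-fold minimum left 42 (6 higher, 36 lower), against 80 (19 higher, 61 lower) with a pseudocount of 0.1 and 81 (16 higher, 65 lower) by voom. Leaving out 1 library gave from 937 without knockdown replicate 1 to 3742 without knockdown replicate 3 (433 to 1558 higher, 504 to 2184 lower), with 1025 without control replicate 1, 1165 without control replicate 3, 1070 without knockdown replicate 2 and 1741 without control replicate 2. Why the count rose without knockdown replicate 3 and fell without each other library, beyond there being fewer libraries, was not tested. Without genes carrying either 7-base word 831 fell, from 10766 tested. The number of lists called was 6, from 4 to 9 elsewhere and 0 with camera's estimated correlation, where the lowest unadjusted p was 0.0887; fry called 9, without the interferon list. The interferon, cell cycle and NRF2 lists were called in all 16 settings with the preset correlation. ESR1 turned sign with quantile normalization (0.0085) at values near 0; the cause was not tested. Of 125 tested named genes, 35 kept their call with the 2-fold minimum. Apart from that, 66 kept it under every alternative fixed beforehand that tested them, 59 were lost in at least 1, 54 of them with no filter, and 0 reversed.

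Over all genes the replicate numbers showed no clear pairing: the deviations of same-numbered libraries correlated at -0.08, 0.20 and 0.01, and control 1 correlated best with knockdown 3 (0.23). The mean of the interferon list, however, kept the same order by number in both groups. It was 4.95, 4.70 and 5.11 in controls 1 to 3 and 4.35, 4.08 and 4.44 in knockdown libraries 1 to 3. Its camera adjusted p at the preset correlation was 5.3e-14 with the number as a block, against 8.5e-09 without. A pairing by number is therefore not excluded. With the number as a replicate block, 2261 genes were called (1051 higher, 1210 lower), and 2015 of the 2371 kept their call and direction; 9 named genes were not called, SNAI1, DST, ERBB3, SESN2, TGFB2, AMOTL1, IRS2, H2BC12 and ERG, with adjusted p from 0.0543 to 0.0777. Depth limits low genes: a gene of 1 kb at 1 FPKM rests on about 17 reads. Alternatives meant for count tables were not run.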

Other observations

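The families and tests in this part, apart from the count of called genes over other splits of the libraries, were chosen after the results had been seen. Of 32 gene families, defined by symbol after an earlier look with slightly different families, 5 were called by camera with the preset correlation, which also called 1 to 5 of the fixed lists when the libraries were split in other ways. Cytosolic ribosomal protein genes had a median log2 fold change of 0.13, with 9 of 82 rising and 0 falling, among them RPL13A from 526 ± 32.7 to 667 ± 43.3 FPKM and RPLP0 from 313 ± 26.2 to 401 ± 25.3 FPKM (SD, n = 3; camera adjusted p = 8.3e-07, and adjusted p = 0.910 with an estimated correlation). RPLP0P6 and RPLP0P9, pseudogene copies of RPLP0 that may share its reads in these tables, are counted in the 9, and the median stayed above 0 with median-ratio scaling (0.15) and quantile normalization (0.07). Tubulin genes had 5 of 8 members rising and 0 falling, with TUBB from 257 ± 13.8 to 329 ± 10.1 FPKM (adjusted p = 0.0128, and adjusted p = 0.910 with an estimated correlation). All histone genes together, 34 measured with the replication histones and some pseudogenes among them, had 11 rising and 0 falling, with the variant gene H2AJ from 21.1 ± 0.71 to 31.7 ± 3.09 FPKM (adjusted p = 0.00014, and adjusted p = 0.473 with an estimated correlation).

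Subunits of the TRiC chaperonin, which folds tubulin and actin, went down: 4 of 8 fell and 0 rose, with CCT8 from 158 ± 3.53 to 133 ± 5.69 FPKM and TCP1 from 69.8 ± 4.61 to 56.4 ± 1.53 FPKM (median -0.15, adjusted p = 0.0193, and adjusted p = 0.824 with an estimated correlation; adjusted p = 0.0515 with median-ratio scaling, and 7 of 8 lower with adjusted p = 0.00061 with quantile normalization). MCM genes, most of which are also in the cell cycle list, had 4 of 9 rising and 0 falling (adjusted p = 0.0328, and adjusted p = 0.700 with an estimated correlation; 0.0515 with median-ratio scaling and 0.0794 with quantile normalization). Of 11 chemokine genes 2 rose and 2 fell, and the family was not called (adjusted p = 0.729): CCL5, an interferon- and NF-kB-induced chemokine, fell from 40.8 ± 5.83 to 21.5 ± 2.80 FPKM. Integrin β1, encoded by ITGB1, fell from 163 ± 5.11 to 125 ± 9.39 FPKM, while ITGB4 rose. B2M, the light chain of HLA class I, fell from 266 ± 31.6 to 216 ± 2.41 FPKM, and it was the 1 called gene among 11 HLA-related genes; 0 were called with median-ratio scaling and 2 with quantile normalization.

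The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real grouping called 2371 genes by limma and the highest of the other 9 splits called 0 (107 to 1679 genes at an unadjusted p under 0.05), so 1 of the 10 splits reached the real count. It called 6 lists by camera with the preset correlation and the highest other split 5, again with 1 of 10 reaching the real count. For the interferon list 2 of the 10 splits reached the real adjusted p of 8.5e-09, and the lowest of the others, that of control replicates 1 and 3 and knockdown replicate 1 against the rest, was 2.0e-14. The words gave an absolute t of 15.6 for CTGATGA and 9.98 for TCGGAGA in the real grouping and at most 14.6 and 8.59 in another split, so 1 of 10 splits reached the real value for each; mixed splits keep part of a difference between the groups, and a t over genes does not weigh its size.

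Genes with CTGATGA in the 3′ UTR were lower in the knockdown. With 3′ UTR length, GC content and expression as covariates, the difference was -0.13 on the log2 scale over 704 genes (t = -15.6). The highest absolute t in 100 shuffles was 4.92. Without covariates, the mean difference from genes lacking the word was -0.17, -0.20 and -0.13 in the 3 knockdown libraries. Letter content alone is argued against: with GC content held fixed in the fit, other words made of the same letters had a median difference of -0.00415. The furthest of them in the same direction, ACTGATG, overlaps CTGATGA and had t = -7.81. CTGATGA came first when chosen in one part of the genes, and in the other part it had a difference of -0.128 (t = -10.8, rank 1). Both parts were measured in the same libraries, so this shows that the difference holds across genes and does not tell its cause. A candidate explanation, read back from the word and not from a known sequence, is silencing by a knockdown siRNA with the seed TCATCAG. Loss of ER-α36 itself cannot be told apart from it, because the labels name 1 targeting siRNA and a second sequence was not analysed here. Of the 1173 searched falling genes 839 lack the word in the 3′ UTR searched, but they may hold other sites. The overlapping word TGATGAA in the 3′ UTR had t = -12.9 over 938 genes. CTGATGA in the coding sequence had t = -7.53 over 1752 genes (difference of -0.044), with the presence of both words in the 3′ UTR held fixed. How many falling genes lack every such site was not counted.

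Genes with TCGGAGA in the 3′ UTR were higher by 0.19 over 118 genes with the same covariates (t = 9.98). Without covariates, the mean difference was 0.21, 0.19 and 0.19 in the 3 knockdown libraries. In the coding sequence the word had a difference of 0.068 over 530 genes (t = 7.42), with the presence of both words in the 3′ UTR held fixed. Letter content alone is argued against here too (median difference of 0.00672 over words of the same letters, with GC content held fixed). The furthest of those words, ATCGGAG, overlaps TCGGAGA and had t = 4.91. CGGAGAA, an overlapping word, was chosen in one part of the genes and had t = 6.71 in the other (rank 2). As the libraries are the same in both parts, this does not tell the cause. A candidate explanation is silencing by a seed of the control siRNA in the control libraries. The pattern extends to words that hold only part of TCGGAGA, with smaller differences for commoner words. GGAGAAA had a difference of 0.061 over 1366 genes (t = 9.04) and AGGAGAA of 0.043 over 1477 genes (t = 6.38). Both share GGAGA with TCGGAGA and lie outside the words of the same letters compared above. Whether they act as partial matches to the same site was not tested. A control duplex in common commercial use was recalled from general knowledge after the word was found. Its sense strand is UUCUCCGAACGUGUCACGU, whose positions 2 to 8 are complementary to TCGGAGA. That match prompted its choice and is no test of it. The site for its antisense strand had t = 3.12 (rank 163 of 15821 words in the higher direction). The highest absolute t over all words in the shuffles was 4.92. That is a limit for a search of all words and not for 1 site, so the value of the antisense site decides nothing. That this duplex was used is a hypothesis, as the labels give no sequence, and a response to loss of ER-α36 stays open.

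Interferon genes were lower in the knockdown. Direct silencing through CTGATGA in the 3′ UTR is argued against, since 1 of the 27 genes (IFI44L) carries the word there and the other 26 had a median log2 fold change of -0.635. This covers that site alone, as overlapping words and coding sequences of these genes were not searched. Scaling of the libraries is argued against, as the median log2 fold change of the list was -0.65 after quantile normalization (18 of 27 lower) and -0.62 with median-ratio scaling (also 18), against -0.64 before. A stronger interferon response to the control siRNA instead of loss of ER-α36 cannot be told apart from an effect of ER-α36, because 0 libraries of untransfected cells were analysed. The call also rests on the preset correlation, as adjusted p = 0.422 with an estimated correlation and 0.0502 by fry, and the list differed between libraries of a group: another split gave a lower adjusted p (2.0e-14) than the real one.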
